A study of Mus musculus with 8 samples.

How the data were processed

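The deposited data were 8 single-colour microarrays of mouse testis RNA, 4 from wild-type and 4 from Vrk1 mutant mice, and samples were assigned to genotype and replicate from the submitters' labels alone. Per the labels' protocols, total RNA was extracted with Trizol, and Cy3-labelled cRNA was made from 0.5 ug of it with Agilent's one-colour Quick Amp kit. Per the submitters' processing notes, signals were extracted with Agilent Feature Extraction 9.5.3.1. Each array held 45018 features, of which 1639 were controls and 43379 measured 41174 distinct probes. The deposited intensity values are the processed signal of each spot, which per the file headers was background-subtracted with spatial detrending and multiplicatively detrended within the array, with surrogate values switched off so that an intensity could be negative. Per the file headers, nothing was scaled between arrays. The mean and local background intensity of each spot, also deposited, are unscaled scanner readings. The deposited value table of the series held the processed signal itself, with all 45018 features of each array equal within a relative tolerance of 1e-04, on a linear scale without centring, and its column medians ran from 97.8 to 205.9.

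Per array, the processed signal was divided by its 75th percentile over non-control features, raised to a floor of 0.01437 of that percentile (the highest of the arrays' lowest scaled signals among probes well above background) and converted to log2. The design written before the data were examined assumed the log2 of the signal without a floor, and the floor was needed because the signal held negative values. Spots that Feature Extraction called outliers were left out, and the 10 spots of each of the 245 repeated probes were averaged. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept, with at least 3 values in each group. This left 33717 probes. Each gene was represented by its passing probe with the highest mean log2 level, which gave 23962 tested genes, 17066 of them with a current symbol. Names came from RefSeq accessions for 22951 probes and from the name in the array files for the other 18223. Of the genes with at least 2 called probes, 1252 in number, 176 had called probes in both directions. Coordinates are those of the array files (mm7), and no genome sequence was used.

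Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 8 arrays, genotype as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. For a gene not well above background on any array of a group, that group's mean rests on values at background level or at the floor. Signals were already raised to the floor, so no separate bound on the fold could be formed. The 22 gene lists (testis cell types, germ cell stages, other tissues and processes) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move, on balance, 1 way. The mean level of each list per array was compared with a two-sided exact permutation test over the 70 arrangements, whose smallest p is 0.0286, and 15 lists reached it. The procedure was tested on simulated data for 23911 genes with 200 changed. It recovered 1.49% of genes changed by 0.5 log2 units, 52.2% of those changed by 1 and 92.4% of those changed by 2, with 6 false calls among 103, and of the 22 lists it called only a Sertoli list raised by 1 log2 unit. The simulated noise was independent between genes, and 200 genes were changed, where 8450 were called in the real data. More calls loosen the cutoff that the adjustment sets, so these recovery rates do not carry over. Independent noise also leaves untested how camera behaves with correlated genes.

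Genes were named by a fixed rule: Vrk1, Vrk2 and Vrk3; Zbtb16, Kit, Stra8, Sycp3, Acrv1, Prm1, Sox9 and Cyp17a1 whatever their result; the 8 largest rises and 8 largest falls among genes with a symbol that passed the test without overlap between groups; and for each list the 2 tested members with the smallest p. Other members of the lists serve as examples of their list, and Ttc8, AK045549, LOC628916, Adam7, Defb42, Ltf, Lcn5 and Lcn8 were singled out after their values were seen. Of the genes picked by this rule, 2 are not reported here. No probe carried the name Zbtb16, so it was not analysed here.

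The number of arrays limits the precision. Correlations of log2 values between arrays were 0.969 to 0.995 within and 0.955 to 0.984 between genotypes. The labels describe biological replicates in independent experiments but do not say which animals they came from. The mean log2 level of the E1A spike-ins was -0.31 ± 0.04 in wild type and -0.27 ± 0.13 in the mutant (SD, n = 4 each; two-sided exact permutation p = 0.571), and no feature was saturated. Each genotype lay on its own slide and scan, so no slide term could be fitted.

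Alternatives fixed beforehand were normexp background correction (offset 50) on the mean and background signals, scaling to the median, quantile normalization, the deposited value table, 3 other filters on dim probes, the mean over a gene's probes, every passing probe tested, a trended and robust variance, array quality weights, the replicate number as a block, a 2-fold threshold and leaving out each array. Alternatives chosen after seeing the data were a floor of 0.005, spike-in scaling, cyclic loess, removal of the medians of blocks of 38 grid rows, and leaving out mutant replicates 1 and 4, with or without wild-type replicate 1. The tests of gene position, signal level, the X chromosome and epididymal transcripts were also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.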

Results

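RNA levels were measured in testes of wild-type mice and of mice homozygous for a disrupted Vrk1 gene, which encodes a serine/threonine kinase of the nucleus. The RNA came from the mixed cells of the testis, germ cells together with Sertoli, Leydig and other somatic cells. Each of the 4 wild-type and 4 mutant samples, described as biological replicates, was hybridised to 1 single-colour Agilent mouse array. The comparison asked how the testis transcriptome differed when Vrk1 was disrupted. Age, litter, strain and the kind of Vrk1 allele are not given in the sources used here. The 75th percentile of the signal was 719 ± 51.3 (SD, n = 4) on the wild-type and 996 ± 87.3 (SD, n = 4) on the mutant arrays (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). Of the features, 76.1% ± 1.93 lay well above background in wild type and 84.3% ± 1.47 in the mutant (SD, n = 4 each; two-sided exact permutation p = 0.0286). The 4 arrays of each genotype shared a slide and a scan of their own, so slide and genotype cannot be told apart in any value given here.

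Vrk1 RNA was 4.78-fold lower in the mutant. The probe that represented the gene (A_51_P102339, chromosome 12, 103556489 to 103557469 in the array's mm7 coordinates) had a log2 signal relative to the array's 75th percentile of -0.71 ± 0.16 in wild type and -2.97 ± 0.19 in the mutant (SD, n = 4 each). The log2 difference of -2.26 had a standard error of 0.15 and a limma adjusted p of 1.56e-04 after Benjamini-Hochberg adjustment. The second probe (A_52_P555672, chromosome 12, 103560461 to 103560520) was 4.17-fold lower, at -1.48 ± 0.06 against -3.54 ± 0.13 (SD, n = 4 each; adjusted p = 1.24e-04 in the fit over all probes). Both probes stayed well above background on all 4 mutant arrays. The disrupted part of the gene is not given in the sources used here, so it is open whether the probes lie inside it. The related kinase genes Vrk2 and Vrk3 fell by 0.53 and 0.54 on the log2 scale (adjusted p = 0.0355 and 0.0134). Vrk2 went from -1.33 ± 0.26 to -1.85 ± 0.19 and Vrk3 from 4.21 ± 0.11 to 3.68 ± 0.13 (SD, n = 4 each). The call of Vrk2 ended in 6 of the 8 fits that each left out 1 array, with differences from -0.64 to -0.43. The fall of Vrk3 was -0.25 with quantile normalization, -0.21 with cyclic loess and -0.41 with normexp background correction, and did not pass the test under any of these.

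**Figure D1:**
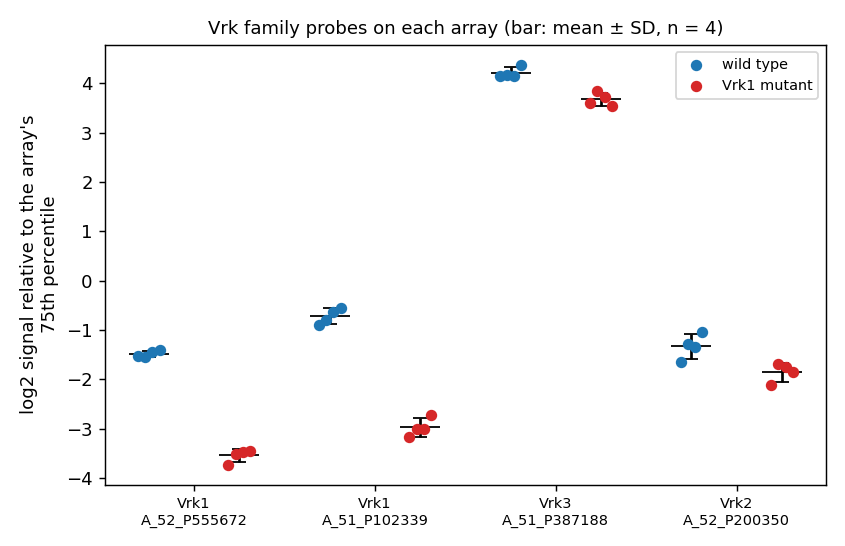
Log2 signal relative to the array's 75th percentile (vertical axis) for each probe of Vrk1, Vrk3 and Vrk2 (horizontal axis) on the 4 wild-type (blue) and 4 mutant (red) arrays, with bars for mean ± SD. The mutant mean minus the wild-type mean is -2.06 and -2.26 for the Vrk1 probes, -0.54 for Vrk3 and -0.53 for Vrk2.

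Across the genome, 5321 genes were higher and 3129 lower in the mutant at a limma adjusted p under 0.05, of 23962 genes tested. Changes of at least 2-fold lay mostly on the higher side, with 1772 genes against 82. The numbers were 822 against 406 with median scaling, 1028 against 289 with quantile normalization and 307 against 42 with normexp background correction. The largest rises that did not overlap between the genotypes were those of Crisp1, Spink8, Serpina3n, Cd52, Igfbp3, Elovl3, Aqp5 and Olfr1090. Serpina3n, a secreted serine protease inhibitor, rose 13.6-fold (log2 3.76, SE 0.42, adjusted p = 6.86e-04) and was well above background on 2 of the 4 wild-type arrays. The water channel gene Aqp5 rose 4.91-fold (log2 2.30, SE 0.41, adjusted p = 0.00472). Elovl3, a fatty acid elongase that was not well above background on any wild-type array, rose 4.97-fold (adjusted p = 6.33e-04). That fold rests on wild-type values at background level and is no lower bound. After normexp background correction its difference was 0.40 and did not pass the test. Igfbp3, which binds insulin-like growth factors, rose 5.69-fold with the probe that represented it (log2 2.51, SE 0.24, adjusted p = 4.11e-04). Its other probe differed by 0.15 (adjusted p = 0.517). The olfactory receptor gene Olfr1090 rose 4.89-fold (log2 2.29, SE 0.23, adjusted p = 5.27e-04). With normexp Serpina3n gave 1.90, Igfbp3 1.08 and Olfr1090 1.06 on the log2 scale, and all 3 passed.

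Vrk1 apart, the largest falls among genes with a symbol and without overlap between the genotypes were those of Kcnk10, Galc, Them5, Mterf3, Tekt3, Olfr1218 and Dot1l. Kcnk10, a potassium channel gene whose probe carries a clone name in the array files, was 4.89-fold lower (log2 -2.29, SE 0.31, adjusted p = 0.0016) and stayed well above background on 2 of the 4 mutant arrays. Another probe under this clone name, 1700024D23Rik, gave 0.035 (adjusted p = 0.883). Galc, which encodes the lysosomal enzyme galactosylceramidase, was 3.29-fold lower (log2 -1.72, SE 0.22, adjusted p = 0.00124). Its other probes gave -0.58 (adjusted p = 0.0327) and 0.07 (adjusted p = 0.864). Tekt3, a tektin of the sperm flagellum, fell by 1.32 on the log2 scale (adjusted p = 0.0113). Them5, an acyl-CoA thioesterase gene, fell by 1.63 (adjusted p = 5.56e-04) and Mterf3, a mitochondrial transcription factor gene, fell by 1.37 (adjusted p = 0.0138). Olfr1218 fell by 1.29 on the log2 scale (adjusted p = 6.98e-04). The histone methyltransferase gene Dot1l fell by 1.26 with 1 probe (adjusted p = 6.00e-04). Its other 2 probes gave 0.04 and 0.17 and did not pass the test. With normexp Kcnk10 gave -1.25 and Them5 -1.01, and both passed.

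The counts depended on how the arrays were scaled. Of the called genes, 63.0% were higher with scaling to the 75th percentile, 33.1% with scaling to the median (3372 higher, 6827 lower) and 41.2% after normexp background correction (1878 higher, 2684 lower). The median log2 difference over all genes was 0.04, -0.18 and -0.22 under these settings. Relative to that median, the Sertoli list lay at 0.88, 0.88 and 1.16 and the late spermatocyte list at -0.61, -0.61 and -0.32. Other scalings kept more higher than lower genes. The higher share of the calls was 62.5% with spike-in scaling (4447 higher, 2672 lower) and 64.5% with cyclic loess. It was 56.8% with quantile normalization and 55.0% with row block medians removed. Without mutant replicates 1 and 4, in which Crisp1, Spink8 and Cd52 were highest, 1109 genes were higher and 230 lower, of which 1097 and 222 were among the genes called with all arrays. Leaving out wild-type replicate 2 or 3, or mutant replicate 1, 3 or 4, lowered the number of lower genes to 1635, 1593, 1644, 1581 and 1793.

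The lists of meiotic and early postmeiotic germ cell genes had medians below 0. They held bright genes, and bright genes fell as a whole, with a median of -0.45 above a mean log2 level of 4. The 31 late spermatocyte and round spermatid genes had a mean level of 4.02. Set against genes of matched level, their median was -0.14, and that of the Sertoli and Leydig genes was 1.21. Most of the fall of these germ cell genes was thus shared with other genes as bright. Of 14 measured genes of late spermatocytes, 8 fell and 6 did not pass the test (12 fell when adjusted over the list alone). Among those that fell were Hspa2, a chaperone of spermatocytes (log2 -0.67, SE 0.16, adjusted p = 0.0147), and Mybl1, a transcription factor of meiosis (-0.62, SE 0.13, adjusted p = 0.00789; other probe -0.19, adjusted p = 0.638). Ccna1, the germ cell A-type cyclin (-0.72, adjusted p = 0.0163), and Cyct, the testis cytochrome c (-0.76, adjusted p = 0.0190), fell as well. Of 17 round spermatid genes, 6 fell and 11 did not pass (7 fell when adjusted over the list alone). The falls included Tbpl1, a TBP-like factor of spermatids (-0.72, SE 0.15, adjusted p = 0.00791), Spata16 (-0.67, SE 0.15, adjusted p = 0.0110) and Acr, which encodes acrosin of the acrosome (-0.66, adjusted p = 0.0121). Other probes of Tbpl1 gave -0.84 (adjusted p = 0.0163), -0.33 (adjusted p = 0.156) and -0.18 (adjusted p = 0.346). Of 18 genes of meiotic prophase, 6 fell (5 when adjusted over the list alone). They included the cohesin subunits Smc1b (-0.61, adjusted p = 0.0102), Rec8 (-0.63, adjusted p = 0.0134) and Stag3 (-0.58, adjusted p = 0.0306) and the synaptonemal complex gene Sycp3 (-0.73, SE 0.25, adjusted p = 0.0484), whose call ended in 6 of the 8 fits that each left out 1 array. Of 10 genes expressed throughout the germ line, Ddx4, Mael, Tdrd1 and Tdrd9 fell (4 also when adjusted over the list alone). Mael, a piRNA pathway gene, fell by 0.59 on the log2 scale (adjusted p = 0.00958). With quantile normalization or cyclic loess, Hspa2 (-0.29 and -0.23), Tbpl1 (-0.34 and -0.28), Spata16 (-0.30 and -0.26), Smc1b (-0.27 and -0.23), Rec8 (-0.31 and -0.27) and Mael (-0.22 and -0.16) did not pass, nor did Mael with normexp (-0.44). With quantile normalization 1 late spermatocyte, 1 round spermatid, 2 meiotic prophase and 0 pan-germ cell genes fell. The list medians were -0.58 for late spermatocytes, -0.51 for round spermatids, -0.44 for meiotic prophase and -0.49 for the pan-germ cell list. Without mutant replicates 1 and 4 they were -0.31, -0.47, -0.15 and -0.20, and 0 members of these lists passed.

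With limma's camera at a preset correlation, adjusted over 22 lists, these 4 lists were lower with adjusted p = 1.44e-04 for late spermatocytes, 1.44e-04 for round spermatids, 0.00153 for meiotic prophase and 0.00711 for the pan-germ cell list. Camera set each list against all other genes without matching them on signal level. With an estimated correlation the adjusted p was 0.413 for the first 3 and 0.418 for the pan-germ cell list, so none of the calls held. On single arrays the mean level of the round spermatid list overlapped between the genotypes (two-sided exact permutation p = 0.0857), with wild-type replicate 4 at -0.17. The other 3 lists did not overlap (two-sided exact permutation p = 0.0286 each). The mean level of the pan-germ cell list on the mutant arrays was -0.56, 0.06, 0.03 and -0.36 for replicates 1 to 4, against 0.13 to 0.25 in wild type. Without mutant replicates 1 and 4, in which Crisp1 was highest, the adjusted p was 0.00182 for late spermatocytes, 2.27e-04 for round spermatids, 0.0685 for meiotic prophase and 0.115 for the pan-germ cell list. With quantile normalization and cyclic loess, the calls of the late spermatocyte (adjusted p = 0.0871 and 0.108), round spermatid (0.0724 and 0.0764) and pan-germ cell lists (0.108 and 0.0950) ended, and normexp background correction ended that of the pan-germ cell list (0.140).

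Of 15 elongating spermatid genes, Prm2, a protamine that packs sperm DNA, fell by 0.41 on the log2 scale (adjusted p = 0.0309). Its call ended in 6 of the 8 fits that each left out 1 array, with normexp (-0.29), with quantile normalization (-0.045) and with cyclic loess (0.22). The other 14, among them Prm1 (-0.30, SE 0.20, adjusted p = 0.256) and Tnp1 (-0.28, adjusted p = 0.248), did not pass (0 fell when adjusted over the list alone). Acrv1, an acrosomal protein gene of round spermatids, gave -0.45 (SE 0.32, adjusted p = 0.287) and passed without wild-type replicate 4 (-0.77, adjusted p = 0.0343) and with array weights (-0.76, adjusted p = 0.0090). The elongating list had a median of -0.15 and an adjusted p of 0.0362 (adjusted p = 0.413 with an estimated correlation), and its median was 0.19 with quantile normalization and 0.28 with cyclic loess. Its call ended without wild-type replicate 1 (0.0583) and without mutant replicate 3 (0.0648). Of 16 genes of undifferentiated spermatogonia, 6 rose (6 when adjusted over the list alone) and 10 did not pass. With median scaling 4 rose and 3 fell, and with normexp 1 rose and 0 fell. The transcription factor genes Foxc2 and Pax7 rose by 1.68 and 1.60 (adjusted p = 0.00941 and 4.96e-04; Pax7 by 0.73 with normexp). Etv5, a GDNF-regulated factor, rose by 0.91 (SE 0.14, adjusted p = 0.00258; 0.18 with normexp, adjusted p = 0.432) and Nanos3, an RNA-binding regulator, by 0.87 (adjusted p = 0.00461). A second probe of Etv5 gave 0.86 (adjusted p = 0.0755). Gfra1, the GDNF receptor, gave -0.19 (adjusted p = 0.464). The list as a whole did not pass (adjusted p = 0.379; 0.606 with an estimated correlation). Its median of 0.08 was -0.13 with median scaling and with quantile normalization, -0.14 with cyclic loess and -0.20 with normexp. Relative to the median of all genes it was 0.048 with scaling to the 75th percentile or the median, 0.023 with normexp, -0.071 with quantile normalization and -0.13 with cyclic loess. Of 9 genes of differentiating spermatogonia, 2 rose and 2 fell (2 and 2 when adjusted over the list alone). Kit, the receptor of stem cell factor, rose by 0.94 (SE 0.15, adjusted p = 0.00314) and Ccnd2, a D-type cyclin, by 0.93 (adjusted p = 0.0299). The 2 genotypes overlapped for Ccnd2, and its call ended in 5 of the 8 fits that each left out 1 array, with median scaling (0.71) and with normexp (0.67). Dmrtb1 fell by 0.66 (adjusted p = 0.0341) and Esx1 fell by 0.42 (adjusted p = 0.0379). Stra8, a gene induced at entry into meiosis, gave -0.16 (SE 0.25, adjusted p = 0.632), and the list gave an adjusted p of 0.561 (0.606 with an estimated correlation).

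Of 22 Sertoli cell genes, 18 rose (20 when adjusted over the list alone) and 4 did not pass. The rises included Wt1, a transcription factor that maintains Sertoli cells (log2 1.12, SE 0.16, adjusted p = 0.00219), and Shbg, the androgen-binding protein gene (1.31, adjusted p = 0.00426). Inha, the inhibin alpha chain gene (1.20, adjusted p = 0.00435), and Sox9, the Sertoli cell determinant (0.95, SE 0.18, adjusted p = 0.00595; other probes 1.03 and 0.72, both passing), rose too. Defb36 rose by 0.97 (SE 0.14, adjusted p = 0.00237). The list median was 0.92, with an adjusted p of 1.81e-07 by camera (adjusted p = 0.413 with an estimated correlation). Without mutant replicates 1 and 4 all 22 members had a difference above 0, 3 of them passing the test (adjusted p = 4.34e-07 for the list). On single arrays the list's mean level was 0.65, 0.19, 0.52 and 0.46 in mutant replicates 1 to 4 and between -0.65 and -0.23 in wild type (two-sided exact permutation p = 0.0286).

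Of 12 genes of Leydig cells and steroid synthesis, 6 rose (10 when adjusted over the list alone). Hsd3b1, a steroid dehydrogenase, rose 2.82-fold (SE of the log2 difference 0.20, adjusted p = 0.00154). Sult1e1, an estrogen sulfotransferase, rose 2.68-fold (log2 1.42, SE 0.29, adjusted p = 0.00736), and Insl3, a Leydig cell hormone, rose by 0.97 on the log2 scale (adjusted p = 0.0269). Cyp17a1, a cytochrome P450 of androgen synthesis, gave 0.76 (SE 0.29, adjusted p = 0.0659), Star 0.79 (adjusted p = 0.0511) and Nr5a1 0.23 (adjusted p = 0.453). Cyp17a1 passed with quantile normalization (adjusted p = 0.0449), cyclic loess (0.0425) and array weights (0.00163), and without wild-type replicate 4 (0.0236) or mutant replicate 2 (0.0433). The list median was 0.90 with an adjusted p of 0.0060 (adjusted p = 0.413 with an estimated correlation).

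Of 17 genes of macrophages and antigen presentation, 10 rose (11 when adjusted over the list alone). They included the lysozyme gene Lyz2 (log2 1.36, SE 0.30, adjusted p = 0.00986), Tyrobp, a signalling adaptor of myeloid cells (1.18, SE 0.26, adjusted p = 0.00903), the complement gene C1qc (1.11, adjusted p = 0.0186) and the growth factor receptor gene Csf1r (0.94, adjusted p = 0.0258). The antigen presentation genes H2-Aa (0.69, adjusted p = 0.130), H2-Ab1 (0.22, adjusted p = 0.330) and Cd74 (0.61, adjusted p = 0.146) did not pass. The list median was 0.74 with an adjusted p of 0.00232 (adjusted p = 0.426 with an estimated correlation). Its level on mutant replicates 1 to 4 was 0.90, -0.15, 0.34 and 0.40, and without mutant replicates 1 and 4 the adjusted p was 0.0331. Leaving out wild-type replicate 1 as well ended the call (adjusted p = 0.0990). The number of members that rose was 5 with median scaling, 5 with normexp and 1 without mutant replicates 1 and 4.

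The lists of peritubular myoid, endothelial and erythroid cells did not pass. Of 10 genes of peritubular myoid and smooth muscle cells, the myosin light chain gene Myl9 (log2 0.80, SE 0.14, adjusted p = 0.00457), the gene of its kinase, Mylk (0.56, SE 0.16, adjusted p = 0.0261; 0.34 with median scaling, not passing), and the actin-binding gene Lmod1 (0.51, adjusted p = 0.0494) rose (2 when adjusted over the list alone). Acta2, smooth muscle actin, gave -0.31 (adjusted p = 0.432). The myoid list gave an adjusted p of 0.285 (0.647 with an estimated correlation) and passed, at 0.00937, with normexp. Of 13 endothelial genes, Cdh5, Pecam1 and Robo4 rose (3 when adjusted over the list alone). Cdh5, the endothelial cadherin, rose by 0.99 (SE 0.23, adjusted p = 0.0118; 0.30 with normexp, adjusted p = 0.204), and Pecam1 by 0.69 (adjusted p = 0.0367; -0.25 with normexp background correction). A second probe of Cdh5 gave 0.72 (adjusted p = 0.164). The endothelial list gave an adjusted p of 0.154 (0.606 with an estimated correlation) and passed, at 0.0450, without wild-type replicate 4. Of the erythroid genes, Alas2, the heme synthesis enzyme, gave 0.48 (adjusted p = 0.0716). It passed with normexp (0.0474), cyclic loess (0.0373) and array weights (0.00415), and without wild-type replicate 4 (0.0345) or mutant replicate 1 (0.0350). The erythroid list gave an adjusted p of 0.219 (0.413 with an estimated correlation).

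**Figure D2:**
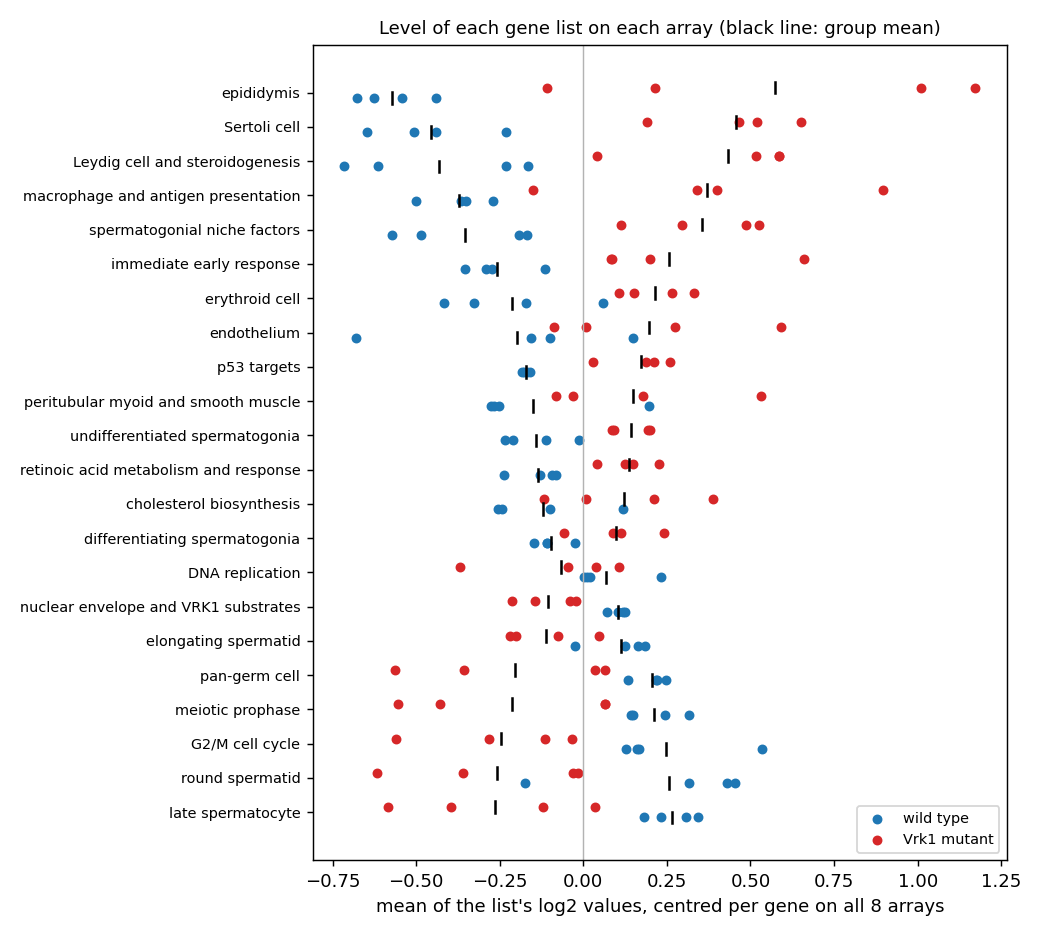
Mean of the centred log2 values of each gene list (vertical axis) on every array (horizontal axis, log2 units), wild type in blue and mutant in red, with a black line at each group's mean. The Sertoli list averages -0.46 in wild type and 0.46 in the mutant, and the late spermatocyte list 0.27 and -0.27, without overlap between the 4 arrays of each genotype.

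Of 21 measured genes of the G2 and M phases of the cell cycle, 11 fell and 10 did not pass (14 fell when adjusted over the list alone). The number that fell was 2 with quantile normalization, 2 with cyclic loess, 6 with normexp and 17 with median scaling. Relative to the median of all genes the list median was -0.60 with scaling to the 75th percentile or the median, -0.27 with quantile normalization, -0.28 with cyclic loess and -0.29 with normexp. They included Ccnb2, a mitotic cyclin (log2 -0.71, SE 0.14, adjusted p = 0.00667), the Aurora kinases Aurkb (-0.83, SE 0.19, adjusted p = 0.0117) and Aurka (-0.84, adjusted p = 0.0213), and Plk1, a polo-like kinase (-0.82, adjusted p = 0.0180). Ccnb2 did not pass with quantile normalization (-0.34) or cyclic loess (-0.29). Cdk1 gave -0.24 (adjusted p = 0.486) and the proliferation marker Mki67 -0.25 (adjusted p = 0.452). This list had a median of -0.56 and an adjusted p of 5.71e-05 (adjusted p = 0.413 with an estimated correlation; 0.00214 without mutant replicates 1 and 4). Of 18 DNA replication genes, 2 rose and 4 fell (2 and 4 when adjusted over the list alone). Pola1, the catalytic subunit of DNA polymerase alpha, rose by 1.06 (SE 0.18, adjusted p = 0.00432; 0.39 with normexp, adjusted p = 0.148) and Tyms, thymidylate synthase, by 0.53 (SE 0.13, adjusted p = 0.0126; 0.32 with median scaling, not passing). Other probes of Tyms gave 0.50 (adjusted p = 0.0226) and 0.35 (adjusted p = 0.0660). Cdc6, Gins1, Mcm7 and the sliding clamp gene Pcna fell, Pcna by 0.47 (adjusted p = 0.0410). The list did not pass (adjusted p = 0.154; 0.606 with an estimated correlation).

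Of 17 p53 target genes, 8 rose (8 when adjusted over the list alone). With median scaling, which shifts all genes of an array alike, 1 rose and 2 fell, and with normexp 3 rose. Relative to the median of all genes the list median was 0.45 with scaling to the 75th percentile or the median and 0.60 with normexp. The 8 included Cdkn1a, a cell cycle inhibitor (log2 0.62, SE 0.15, adjusted p = 0.0136; 0.40 with median scaling, not passing), the sestrin gene Sesn1 (0.86, SE 0.15, adjusted p = 0.00414), Bax, a promoter of apoptosis (0.51, adjusted p = 0.0150), and the death receptor gene Fas (0.54, adjusted p = 0.0164). Other probes of Sesn1 gave 0.46 (adjusted p = 0.0596) and 0.57 (adjusted p = 0.143). Mdm2 gave -0.21 (adjusted p = 0.229). The list median was 0.49 with an adjusted p of 0.0398 (adjusted p = 0.413 with an estimated correlation). The call ended with median scaling (0.0929) and without wild-type replicate 1, 2 or 3 (0.0583, 0.0609 and 0.0526) or mutant replicate 3 (0.0622). It ended as well with the replicate block (0.0503), row block removal (0.0642) and the mean over a gene's probes (0.0534). Of 9 genes for factors of the spermatogonial niche, Kitl, Fgf9, Csf1 and Inhba rose (6 rose when adjusted over the list alone). Kitl, which encodes stem cell factor, rose by 1.24 (SE 0.27, adjusted p = 0.00922) and Fgf9 by 1.26 (SE 0.27, adjusted p = 0.00925; 0.094 with normexp, adjusted p = 0.713). Gdnf gave 0.61 (adjusted p = 0.0742). That list gave a median of 0.76 and an adjusted p of 0.0362 (adjusted p = 0.413 with an estimated correlation), a call that ended without wild-type replicate 1 (0.0583) and without mutant replicates 1 and 4 (0.0946).

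Of 13 genes of the nuclear envelope and known substrates of the VRK1 kinase, 4 fell (4 when adjusted over the list alone). These were Lmnb2, a nuclear lamin (log2 -0.60, adjusted p = 0.0434), Coil, the coilin of Cajal bodies (-0.55, adjusted p = 0.0400), the transcription factor gene Atf2 (-0.56, SE 0.13, adjusted p = 0.0111) and Trp53, which encodes p53 (-0.54, SE 0.13, adjusted p = 0.0124). A second probe of Trp53 rose by 0.59 (adjusted p = 0.0412) and the mean over both probes was 0.02. The other 3 probes of Atf2 did not pass. Banf1, the chromatin-bridging substrate of VRK1, gave -0.27 (adjusted p = 0.172). The list median was -0.31 with an adjusted p of 0.0410 (adjusted p = 0.413 with an estimated correlation). It ended as a call without wild-type replicate 1 or 4 (0.0583 and 0.0657), without mutant replicate 4 (0.0768) and with quantile normalization (0.215).

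Genes of other pathways moved in both directions or did not pass as lists. Of 15 genes of retinoic acid metabolism and response, 6 rose and 2 fell (7 and 2 when adjusted over the list alone). The dehydrogenase genes Aldh1a1 (log2 0.95, SE 0.23, adjusted p = 0.0149) and Aldh1a3 (0.73, SE 0.20, adjusted p = 0.0208) rose, and Aldh1a2 fell by 0.54 (adjusted p = 0.0442). The genotypes overlapped for Aldh1a1. The call of Aldh1a3 ended in 4 of the 8 fits that each left out 1 array and with median scaling (0.51). The list gave an adjusted p of 0.333 (0.437 with an estimated correlation), and its median of 0.34 was -0.22 with normexp. Of 19 genes of cholesterol synthesis, 6 rose and 4 fell (7 and 5 when adjusted over the list alone). Ebp, a sterol isomerase, rose by 1.21 (SE 0.23, adjusted p = 0.00565). The cholesterol list gave an adjusted p of 0.716 (0.866 with an estimated correlation). Of 9 immediate early genes, Ier3, Zfp36, Junb, Ier2 and Egr1 rose (5 when adjusted over the list alone). Ier3 rose by 1.22 (SE 0.16, adjusted p = 0.00134) and Zfp36, which encodes an mRNA decay factor, by 0.84 (SE 0.15, adjusted p = 0.00456). With normexp they gave 0.26 and 0.21 and did not pass. That list gave an adjusted p of 0.0619 (0.437 with an estimated correlation) and passed without wild-type replicate 4 (0.0450), mutant replicate 2 (0.0423) or mutant replicate 3 (0.0407).

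Crisp1, which encodes a secreted protein of the epididymis that coats sperm, had the largest rise among the genes named by size (log2 4.91, SE 1.39, adjusted p = 0.0244), and the rise was unequal among the samples. Its log2 level was 2.50, -2.40, -4.20 and 2.80 in mutant replicates 1 to 4 and between -5.56 and -4.98 in wild type. Spink8, a protease inhibitor gene, was also highest in mutant replicates 1 and 4, at 3.02, -1.23, -1.33 and 1.74 (log2 rise 3.79, SE 0.89, adjusted p = 0.0127). Cd52, a surface glycoprotein of leukocytes and the epididymis, was highest in the same replicates, at 4.03, -0.15, -0.82 and 3.15 (8.59-fold rise, SE 0.98 on the log2 scale, adjusted p = 0.0355). Of 7 tested genes of the epididymis list, Crisp1 and the ribonuclease-like gene Rnase9 (1.60, SE 0.34, adjusted p = 0.00862) rose (2 when adjusted over the list alone) and 5 did not pass, among them Gpx5 (0.23, adjusted p = 0.380). Rnase9 was well above background on 1 wild-type array. With normexp Rnase9 gave 0.052 (adjusted p = 0.871) and Crisp1 3.03 (adjusted p = 0.0588). With array weights Crisp1 gave 2.92 and Cd52 1.71, and neither passed. The list had a median of 0.25, a mean of 1.14 and an adjusted p of 0.205 (0.413 with an estimated correlation). The median was -0.07 with normexp and -0.02 with quantile normalization. Leaving out single arrays gave between 3.87 and 6.20 for Crisp1 and between 2.28 and 3.89 for Cd52, with the adjusted p above the threshold in 3 and 5 of the 8 cases.

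**Figure D3:**
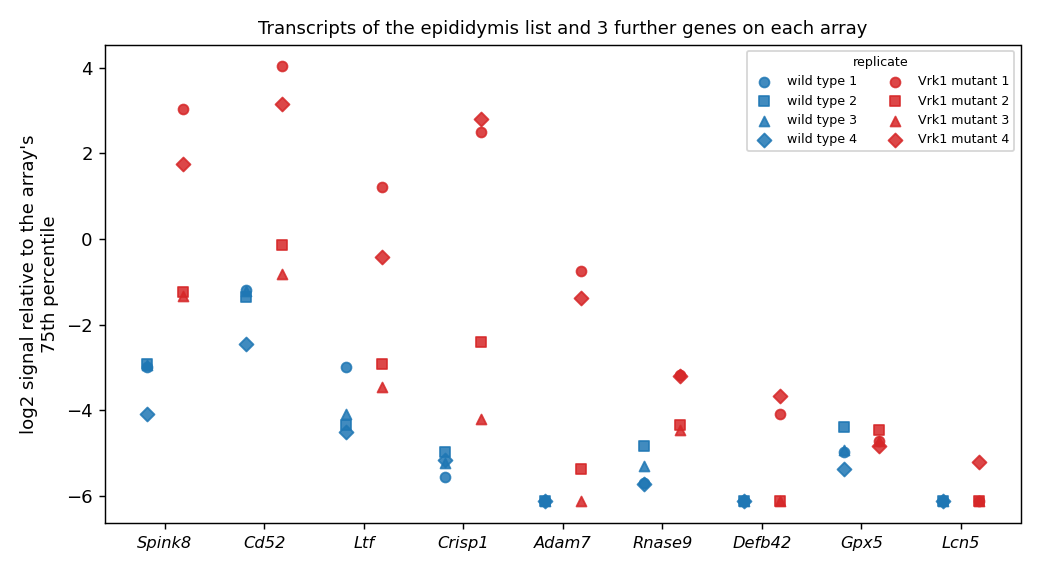
Log2 signal relative to the array's 75th percentile (vertical axis) of members of the epididymis list and of Spink8, Cd52 and Ltf (horizontal axis), with 1 symbol per replicate, wild type in blue and mutant in red. Crisp1 reaches 2.50 and 2.80 in mutant replicates 1 and 4 and lies at -2.40 and -4.20 in replicates 2 and 3, while Gpx5 lies between -5.37 and -4.39 on all arrays.

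Several genes that were at least 2-fold lower lay near Vrk1. Within 10 Mb of Vrk1 on chromosome 12, 5 of 247 genes (2.02%) were at least 2-fold lower, against 74 of 23501 elsewhere (0.315%). The odds ratio was 6.54 (two-sided Fisher's exact p = 0.00141, adjusted p = 0.00423 over 3 such comparisons), in a test chosen after Galc and Kcnk10 were seen to lie there. They were Galc, Kcnk10, the cilium gene Ttc8 (log2 -1.07, adjusted p = 0.0140) and the unnamed transcripts AK045549 (-1.73, adjusted p = 0.0297) and LOC628916 (-1.58, adjusted p = 0.00223). Genes at least 2-fold higher made up 21 of the 247 (8.50%), among them Serpina3n, and 7.37% of the others (odds ratio 1.17, two-sided Fisher's exact p = 0.463). Falls of any size were found for 41 of the 247 (16.6%) and for 13.0% of the others (odds ratio 1.33, two-sided Fisher's exact p = 0.106, adjusted p = 0.158).

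**Figure D4:**
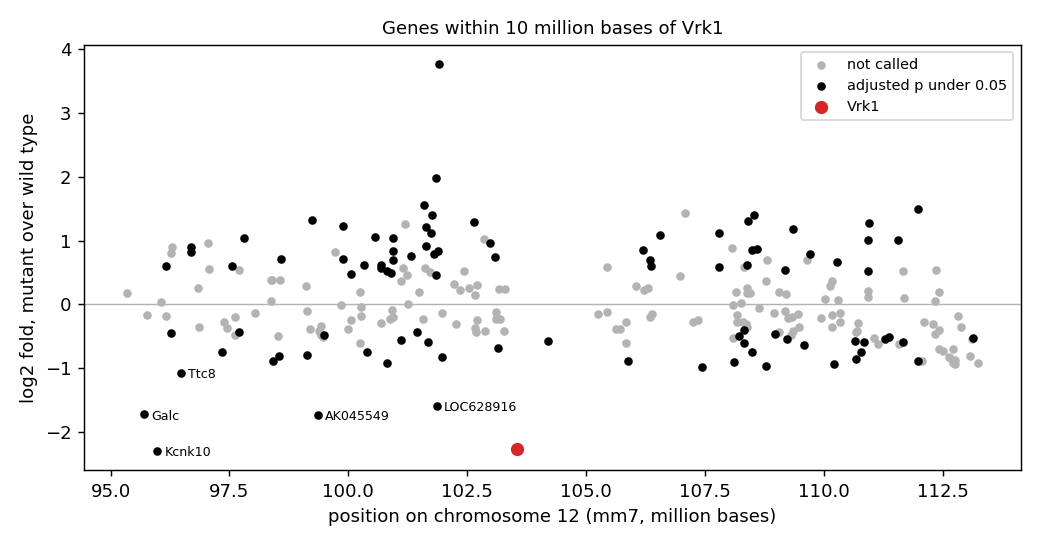
Log2 difference between mutant and wild type (vertical axis) against position on chromosome 12 in Mb of mm7 (horizontal axis) for the genes within 10 Mb of Vrk1, black where the adjusted p passed and gray where it did not. The 5 named genes at least 2-fold lower, from -2.29 for Kcnk10 to -1.07 for Ttc8, lie on the lower-coordinate side of Vrk1 (red, -2.26).

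The direction of change varied with signal level. Genes with a mean log2 level under -5 had a median difference of 0.55, with 45.6% higher and 1.62% lower in the mutant, and those above 4 had a median of -0.45, with 2.89% higher and 40.5% lower. The slope over 22533 genes was -0.085 per log2 unit of level (SE 0.0013), taken across genes, which are not independent replicates. The filter on dim probes could be met by the 4 arrays of 1 genotype alone, and more features lay well above background in the mutant. Of the genes called higher, 502 were not well above background on any wild-type array. Of those called lower, 0 were in the opposite case. The filter can thus favour rises among dim genes. The trend went on among brighter genes, from a median of -0.01 at levels of -1 to 0 to -0.45 above 4, which argues against the filter as its only source. Genes at least 2-fold higher still outnumbered those lower without a filter (1566 against 69). With probes well above background on all 8 arrays the numbers were 1066 against 77. The slope was not fitted under these other filters.

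**Figure D5:**
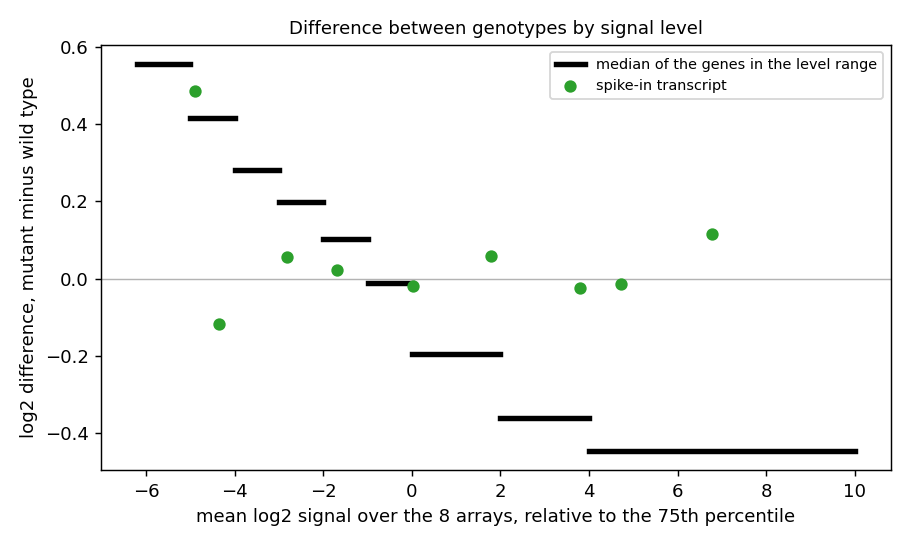
Median log2 difference between mutant and wild type (vertical axis) of genes in ranges of mean log2 level relative to the 75th percentile (horizontal axis, black bars), with spike-in transcripts as green points. The gene medians go from 0.55 in the dimmest range to -0.45 in the brightest, and the spike-in differences lie between -0.12 and 0.48.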

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

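The tests in this part on genes near Vrk1, on epididymal transcripts, on the spike-ins and on cell type lists were chosen only after the results were seen, while the counts over splits of the samples were set beforehand. For probe position, the rule for reading the test was written before it was run, but the removal of row block medians was chosen after seeing the data.

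Of the 35 splits of the 8 arrays into 4 and 4, only the real one called as many genes. It called 8450 genes, and the highest other split called 10. Were the arrays interchangeable, the real split would rank first in 1 of 35 cases, the smallest share this count can give. The other splits mix genotypes and slides, so that difference adds to their spread within groups and few calls follow. The rank argues against chance without excluding it, and cannot tell genotype from slide. For the gene lists, 6 of the 35 splits called 12 or more, as the real one did, and the highest other split called 14. Each of the other splits that called as many put 3 arrays of 1 genotype with 1 of the other. Such splits keep part of the difference between genotypes and do not show what chance alone gives. The count therefore does not decide whether chance gave the number of lists.

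The genes at least 2-fold lower gathered near Vrk1 (Galc, Kcnk10, Ttc8, AK045549 and LOC628916). The two-sided Fisher's exact p of 0.00141 followed from seeing Galc and Kcnk10 there, and for falls of any size the p was 0.106. Without these 2 genes, and with the lowest p over 4 windows of 2 to 20 Mb on either side of Vrk1, the permutation p over genes was 0.0540, so chance placement is not excluded. A sequence difference under single probes remains open, because only 2 other passing probes were assigned to these genes, both to Galc, and 1 of them also passed the test for a fall. A further probe under the clone name of the Kcnk10 probe, 1700024D23Rik, did not fall (0.035, adjusted p = 0.883). A linked chromosome segment kept from another strain around the disrupted gene may also account for the falls: its neighbours showed no excess of rises (odds ratio 1.17), but such a segment need not bring rises, so this excludes nothing. An effect of the Vrk1 disruption on these genes and a difference between the 2 slides were not tested and stay open.

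Crisp1, Spink8 and Cd52 were far higher in mutant replicates 1 and 4 than in 2 and 3, and so was Adam7, an epididymal gene, at -0.74 and -1.37 against -5.36 and the floor. RNA of epididymal tissue in those 2 samples is a candidate explanation: the 10 members of the epididymis list seen on any array ranked the 4 mutant arrays with a Kendall's W of 0.223 against a median of 0.109 for random level-matched sets. A share of 0.172 of 10000 such sets was as high, so this test decided nothing. Defb42 (-4.08 and -3.67 against the floor) and Rnase9 (-3.17 and -3.19 against -4.34 and -4.45) were highest in the same 2 replicates. The abundant epididymal transcripts Lcn5, Lcn8 and Gpx5 had a median rise of at most 0.086 on any mutant array while Crisp1 rose by 8.03. They lay near the floor, Lcn5 rose by 0.92 in mutant replicate 4, and Lcn8 was not well above background on any array, so whole epididymis in a fixed share is not excluded. A single epididymal segment and the genotype stay open as well, and the labels name no tissue other than testis.

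Dim genes rose and bright genes fell, with a slope of -0.085 per log2 unit of level. The filter on dim probes can favour rises among dim genes. The medians went on falling among brighter genes, from -0.01 at levels of -1 to 0 to -0.45 above 4, which argues against the filter as the only source. The slope was not fitted under other filters. The slope over the 9 spike-ins at levels from -5 to 8 was -0.011 (SE 0.015). Those at levels above -4 differed by -0.03 to 0.12, which argues against compression of the signal on 1 slide for such levels. Below that level the spike-ins gave 0.48 and -0.12, so they decide nothing for the dim genes. Shifts between row blocks did not give the genes' slope, which stayed at -0.085 after the medians of row blocks were removed. This removal moves all genes of a block alike whatever their level, so it tests no other effect of probe position. A lower share of germ cell RNA was tested by setting the other cell types side by side. If every other cell type rose alike, the myoid and endothelial lists should match the Sertoli list, and the difference in medians was 0.49, with a permutation p of 1e-05 over genes (the smallest that 100000 permutations can give, with genes taken as independent) but a two-sided exact permutation p of 0.0571 over arrays (-0.28 ± 0.45 against 0.28 ± 0.27, SD, n = 4 each). A lower germ cell share with all other cell types alike therefore cannot be told apart from unequal changes among somatic cells, and the slide remains open as well.

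In 13 of 182 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20 groups, or 9.1. Wild-type replicate 4 held 7 of them. Relative to the mean of the other 3 wild-type arrays it was higher by 0.22 for Vrk3, lower at -0.63 for Prm1, -1.15 for Spink8 and -1.21 for Cd52, and higher by 0.46 for the myoid list, 0.38 for the G2 and M phase list and 0.22 for the DNA replication list. Wild-type replicate 1 was higher by 0.61 for Hsd3b1 and by 0.38 for Wt1. Mutant replicate 2 was lower for Aldh1a1 (-0.74) and for the Leydig cell list (-0.52), and mutant replicate 3 was higher by 0.25 for Tyms. Mutant replicate 4 had 2.92 percentage points more features well above background than the other mutant arrays averaged.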

How the results depend on the processing

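All settings are compared with the values of the report; the lower floor, spike-in scaling, cyclic loess, row block removal and the 2 sets of left-out samples were chosen after seeing the data. Vrk1 stayed lower and past the threshold in all 25 settings (-2.48 to -1.83). Among single named genes, 1409 of 1618 values kept direction and side of the threshold, 177 fell short of it, 21 newly passed and 11 reversed. Where a cause is not stated below, the cause was not tested. Signal over background limits the dim genes, of which 502 called higher were not well above background on any wild-type array. The deposited value table gave the same values.

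With an estimated correlation all 12 called lists fell short, at 0.413 (macrophage 0.426, pan-germ 0.418). The shared value came from the adjustment over lists. Before it, the camera p of these lists ran from 0.0687 (Sertoli) to 0.271 (macrophage). By fry, adjusted p was 0.0146 for undifferentiated and 0.0400 for differentiating spermatogonia, 0.0154 for erythroid cells, 0.0106 for the epididymis and retinoic acid lists and 0.0170 for immediate early genes. At least 2-fold, 1772 genes were higher and 82 lower.

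Normexp gave 1878 higher genes, reversed Pecam1 (-0.25) and the undifferentiated list (0.942). It ended the calls of the pan-germ (0.140), elongating (0.865) and nuclear envelope lists (0.405) and added myoid (0.00937), cholesterol (0.0102) and immediate early lists (0.0250). Median scaling gave 3372 higher and 6827 lower genes and ended the p53 call (0.0929). Quantile normalization gave 3436 higher genes, reversed Stra8 (0.051), Prm1 (0.020) and the elongating list (0.329). It ended the pan-germ (0.108), late spermatocyte (0.0871), round spermatid (0.0724), niche (0.0664) and nuclear envelope calls (0.215). Cyclic loess reversed Stra8 (0.091), Prm1 (0.35), Prm2 (0.22), the undifferentiated (0.976) and elongating lists (0.0796). It ended the pan-germ and niche (0.0950 each), late spermatocyte (0.108), round spermatid (0.0764) and nuclear envelope calls (0.192). Row block removal ended the p53 (0.0642) and nuclear envelope calls (0.0518).

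Without a filter the niche call ended (0.0530); with the filter on all 8 arrays, which tests fewer genes, the elongating (0.0770) and nuclear envelope calls (0.0873) ended and immediate early genes passed (0.0262). The mean over probes gave 0.021 for Trp53, whose probes oppose each other, and 0.55 for Sox9, of which 1 dim probe lacked a value on 1 wild-type array. It ended the p53 and niche (0.0534 each) and nuclear envelope calls (0.131). Array weights gave 6386 lower genes and 0.076 for Stra8.

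Same-numbered samples of the genotypes had correlations of deviations from 0.081 to 0.595, 3 of 4 over 0.1 where all 4 were required, so the numbers were not taken as pairs, although 7 of 8 samples correlated best with their own number. With the replicate block, 6622 genes were higher and 4675 lower, p53 targets gave 0.0503 and the nuclear envelope list 0.0773, no other list call changed, and Cyp17a1 (0.0141) and Alas2 (0.0289) passed.

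Without mutant replicates 1 and 4 (fewer samples), 1109 genes were higher and 230 lower, and Stra8 gave 0.26. Lists gave 0.115 (pan-germ), 0.0685 (meiotic prophase), 0.0503 (p53), 0.0946 (niche), 0.127 (nuclear envelope) and, reversed, 0.664 (cholesterol). Leaving out wild-type replicate 1 as well gave 2099 and 577 genes and 0.34 for Stra8. Lists then gave 0.101 (pan-germ), 0.0837 (meiotic prophase, elongating), 0.0990 (macrophage, p53), 0.117 (niche), 0.156 (nuclear envelope) and, reversed, 0.894 (myoid) and 0.583 (endothelium).

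Leaving out each array gave 3713 to 5391 higher and 1581 to 3745 lower genes, -0.33 to 0.065 for Stra8 (reversed without mutant replicate 1). The adjusted p ranged over 0.0156 to 0.0648 (elongating), 0.0221 to 0.0622 (p53), 0.0192 to 0.0583 (niche), 0.0303 to 0.0768 (nuclear envelope), 0.0450 to 0.409 (endothelium), 0.0407 to 0.1199 (immediate early) and 0.367 to 0.956 (cholesterol, reversed without mutant replicate 1). Of the 8 such fits, the calls of Pecam1 and Prm2 ended in 6, Ccnd2 in 5 and Mylk and Aldh1a3 in 4.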

Other observations

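The tests in this part were chosen after the data were seen, as were the X-linked and olfactory receptor genes as groups.

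Genes of the X chromosome were higher in the mutant more often than autosomal genes. Of 843 tested X-linked genes, 381 rose and 34 fell, against 4845 and 3035 of 22647 autosomal genes. The median log2 difference was 0.47 for X-linked and 0.03 for autosomal genes. Ebp (1.21), Pola1 (1.06) and Alas2 (0.48, not passing), named for their lists, lie on the X chromosome. Compared at matched signal level, X-linked genes lay above autosomal genes by a median of 0.30 (mean 0.26, permutation p = 1e-05 over genes, the smallest that 100000 permutations can give). The mean centred level of X-linked genes minus that of autosomal genes was 0.20, 0.04, 0.14 and 0.23 in mutant replicates 1 to 4. In wild type this difference lay between -0.19 and -0.11 (two-sided exact permutation p = 0.0286). Relative to the median of all genes, the X-linked median was 0.44 with scaling to the 75th percentile, to the median and to the spike-ins, 0.31 with quantile normalization, 0.32 with cyclic loess and 0.17 with normexp background correction, where the X-linked median itself was -0.05.

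Olfactory receptor genes, which encode odorant receptors and of which some are transcribed in testis, moved mostly upwards under all scalings but normexp. Of 732 tested genes of the family, 314 rose and 40 fell, with a median of 0.54 that was -0.10 after normexp background correction, where 66 rose and 51 fell (0.12 relative to the median of all genes there). With median scaling 230 rose and 81 fell, with quantile normalization 181 and 81, and with cyclic loess 201 and 77. Most of these genes were dim, with a median log2 level of -3.27, and at matched level their median was 0.21. The family held both a gene among the largest rises, Olfr1090, and a gene among the largest falls, Olfr1218.

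On wild-type replicate 1 the values were more scattered in part of the array. Between grid rows 115 and 152 the SD of the gene deviations from the group mean was 0.896, against at most 0.500 on the other arrays, and between rows 153 and 190 it was 0.714 against at most 0.461. The median log2 difference between genotypes varied over the grid, from 0.35 in rows 1 to 38 to -0.13 in rows 343 to 380.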
